A study of Arabidopsis thaliana with 6 samples.

How the data were processed

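Transcripts in total RNA were measured by sequencing in 6 samples of Arabidopsis thaliana root tips, 3 from the Col-0 wild type and 3 from the hsl2 mutant, each from the outermost 0.5 mm of primary roots of seedlings aged 7 days. Per the labels' protocols, seedlings grew on vertical agar plates without sucrose under 16 h of light and 8 h of dark, total RNA was extracted with TRIzol and cleaned on RNeasy columns, and stranded Illumina TruSeq libraries were made. Per the submitters' processing notes, the authors used Trimmomatic 0.33, STAR 2.5.1b and featureCounts, whose version is not given. The values are raw counts of reads per gene as deposited by the authors, 1 file per sample, neither normalized nor pooled. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies, may therefore be split in ways that cannot be checked, and no coordinates are printed.

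The files held 37336 gene identifiers, with 0 entries that name no gene. Of these, 37051 matched a locus of the TAIR10.1 reference annotation and 36125 had a product description there. That reference served for gene symbols, descriptions, gene neighbourhoods, GC content and transcript length. Total counts per library ran from 15051468 to 20468890. A count of 3 corresponded to between 0.147 and 0.199 CPM (counts scaled by library size), which sets the level below which single libraries carry little information.

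Groups were taken from the sample titles. The comparison of hsl2 with wild type was fitted on all 6 libraries in R 4.3.3 with edgeR 4.0.16, using its filter on low counts (filterByExpr), TMM normalization and the quasi-likelihood F-test with genotype as the only term, which left 4 residual degrees of freedom. It tested 17989 genes. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Fold changes are log2 of hsl2 over wild type, standard errors were derived from the F statistic, and CPM values use the TMM library sizes. Nothing in the labels says whether the samples of a genotype came from separately grown plants, so p-values measure the spread between these samples, which may be partly technical.

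In all, 40 gene lists were fixed before the data were examined, 30 by locus and 10 by words in the gene description. A list needed at least 5 tested genes, which left 39. Lists were tested with camera from limma 3.58.1 with the preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 39 lists. The test was repeated with a correlation estimated for each list, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Lists built from descriptions also took in entries that share only a word: the ribosomal protein list holds organellar-type proteins, and the extensin list is largely made of the Pollen Ole e 1 and extensin family. Genes past the threshold within 1 Mb of HSL2 were counted. The share of genes at an unadjusted p under 0.05 in that window was compared with that of all other tested genes by a two-sided Fisher's exact test, added after the data were seen.

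The rule for named genes was also set before the data were examined. It named 11 genes whatever their result, those with the largest changes past the threshold, the 5 with the smallest p in each direction, and up to 4 members of each list past the threshold. If fewer than 10 genes passed, the 10 with the smallest p were to be named with values only, and this applied. Members of lists past the camera threshold were named by smallest p, as were all tested cell death genes and the clock genes, after their values were seen.

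Alternatives set beforehand were RLE size factors, upper-quartile normalization, no filter, a filter of at least 1 CPM in at least 3 samples, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, a threshold of 0.01, and edgeR's test against a fold change of 1.5. Voom with library quality weights, and a fit without hsl2 replicate 1 and wild type replicate 3, were added after the data were seen. Gene calls with edgeR, DESeq2 and limma-voom were tested on simulated data for this comparison. Camera with the preset correlation was run there too, but genes drawn independently cannot test whether that correlation holds in the real data. The 17989 genes were drawn independently from the real means, library sizes and spread, with 200 of them changed. A further list of 20 genes was shifted by a log2 fold change of 0.6. The other calculations were not simulated. edgeR recovered 65.7% of genes changed 2-fold and 97.0% of those changed 4-fold, but 5.97% of those changed 1.5-fold, with 14 false calls among 129. DESeq2 recovered 76.1%, 98.5% and 22.4%, with 22 false calls among 156.

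No library was a duplicate of another: the chi-square statistic per degree of freedom over the tested genes lay between 6.17 and 36.7 for pairs of the same genotype, far above sampling noise.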

Results

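The transcriptome of the outermost 0.5 mm of the primary root was compared between wild type Arabidopsis thaliana of the Col-0 accession and the hsl2 mutant at 7 days. This piece of the root holds the root cap, which sheds its outer cells as the root grows, the stem cells and the division zone. HSL2 is a receptor-like kinase of the HAESA family, known from floral organ abscission, where it acts with HAE as a receptor of the IDA peptide. The series was designed to find how the mutation affects sloughing of the root cap. Each genotype had 3 libraries. Total gene counts were 20468890, 15791819 and 15994514 in wild type replicates 1 to 3, and 15051468, 19353957 and 15438666 in hsl2 replicates 1 to 3. Between 21302 and 21866 genes had at least 1 count in a library.

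A pair of libraries stood apart from the others of their genotype. The hsl2 1 library held transcripts of green tissue: the light-harvesting gene LHCB1.3 was at 40.4 CPM there and between 3.25 and 8.31 CPM in the other 5 libraries, and the Rubisco small subunit gene RBCS1A at 16.7 CPM against 1.23 to 3.24 CPM. Its share of mitochondrial counts was 0.0614% against 0.0176% to 0.0289%, and its TMM factor of 0.934 was the lowest. The share of chloroplast-encoded counts, 0.00157%, was close to that of hsl2 2, 0.00152%. Why hsl2 1 stood apart was not tested. The wild type 3 library held more root hair transcripts than the other wild type libraries, with COBL9 at 7.77 CPM against 1.67 and 4.12 CPM and EXPA7 at 5.83 CPM against 0.443 and 0.615 CPM. The mean log2 CPM of the root hair and epidermis list, relative to its mean over all libraries, was 0.41 in wild type 3, -0.69 and -0.67 in wild type 1 and 2, and between 0.11 and 0.48 in the hsl2 libraries. The first principal component took 40.6% of the variance, with wild type at -27.5, -34.3 and -4.37 and hsl2 at 48.8, 10.1 and 7.26. The genotypes differed in sign there, but wild type 3 lay nearer to hsl2 2 and hsl2 3 than to wild type 1 and 2. The hsl2 1 library was the farthest from the others. The second component took 27.5% and placed wild type 3 at -13.4, on the side of hsl2 2 and hsl2 3. The chi-square statistic per degree of freedom also set wild type 3 closer to these hsl2 libraries than to its own genotype. It was 13.32 and 12.73 with hsl2 2 and hsl2 3, against 17.003 and 21.52 with wild type 1 and 2.

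HSL2 (AT5G65710) transcript was present in both genotypes, with no lower mean in hsl2. It was at 6.98, 8.61 and 7.22 CPM in the wild type libraries and 7.61, 9.76 and 9.81 CPM in the hsl2 libraries, from 107 to 193 counts per library. The means were 7.61 ± 0.881 CPM (SD, n = 3) and 9.06 ± 1.25 CPM (SD, n = 3), a log2 fold change of 0.26 with a standard error of 0.18 (adjusted p = 0.537, edgeR). The labels do not give the allele, so this level does not check the genotype of the libraries. HAE (AT4G28490), the receptor that acts beside HSL2 in abscission, was at 1.62 ± 0.310 CPM in wild type and 1.40 ± 0.533 CPM in hsl2 (SD, n = 3 each). IDA (AT1G68765) had 0 counts in all 6 libraries, which allows up to 0.147 to 0.199 CPM. IDL1 (AT3G25655), an IDA-like peptide gene, had 4 to 13 counts per library and was not tested. The list of IDA, HAE and HSL2 signalling components had a median log2 fold change of -0.11 over 17 tested members (camera adjusted p = 0.324). Its median was -0.17 without hsl2 1 and -0.03 without wild type 3.

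**Figure D1:**
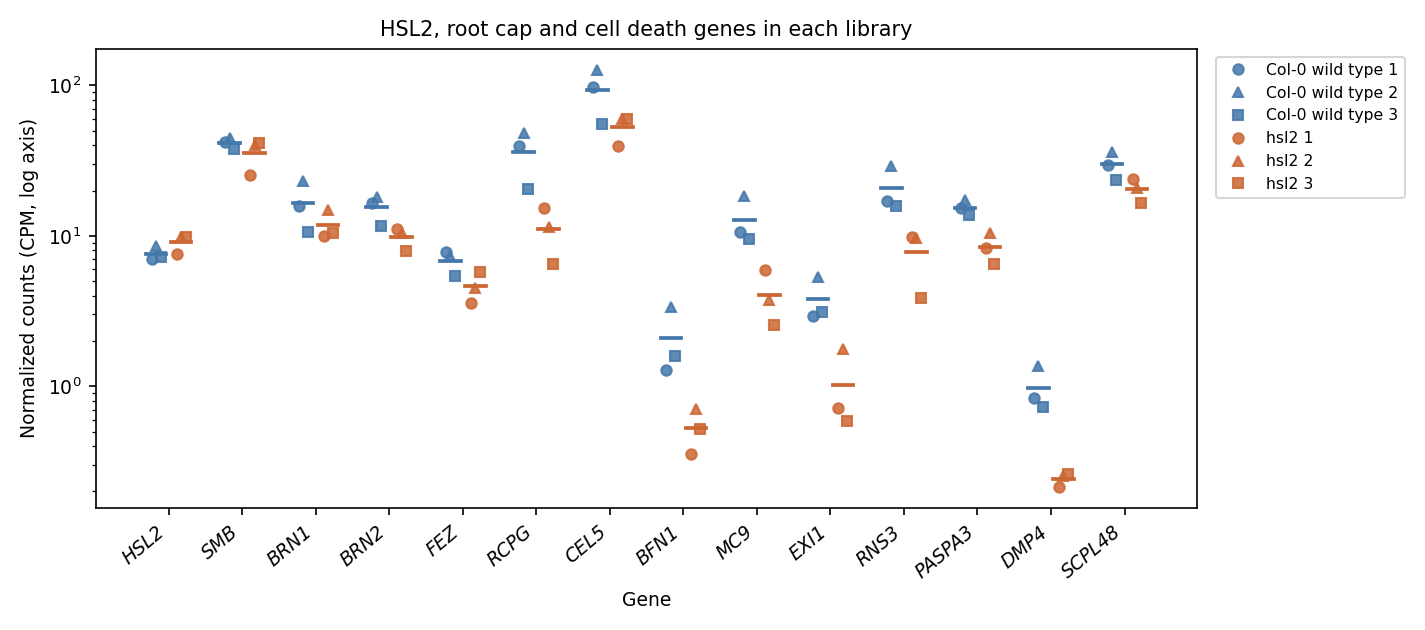
Normalized counts (CPM, log axis) of HSL2, root cap genes and cell death genes in each library, with symbols for replicates and bars for the mean of 3 libraries per genotype. HSL2 overlaps between genotypes, while RCPG, BFN1, MC9, EXI1, RNS3, PASPA3 and DMP4 are lower in each hsl2 library than in any wild type library.

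Genes of developmental programmed cell death, which mark the last stage of root cap cells, were lower as a group in hsl2. The 7 members, 7 of them tested, had a median log2 fold change of -1.66, and 7 were lower (camera adjusted p = 7.12e-08, or adjusted p = 0.355 with an estimated correlation). Adjusted over the list alone, 7 members passed the edgeR test, against 0 over all genes tested. The metacaspase gene MC9 (AT5G04200) was at 12.8 ± 4.80 CPM in wild type and 4.07 ± 1.70 CPM in hsl2, and the nuclease gene BFN1 (AT1G11190) at 2.08 ± 1.14 and 0.529 ± 0.176 CPM (SD, n = 3). The ribonuclease gene RNS3 (AT1G26820) was at 20.7 ± 7.42 and 7.80 ± 3.42 CPM, and the aspartic protease gene PASPA3 (AT4G04460) at 15.4 ± 1.76 and 8.41 ± 1.97 CPM (SD, n = 3). Log2 fold changes were -1.83 for EXI1, -1.96 for DMP4, which reached at most 1.35 CPM, and -0.55 for SCPL48. With DESeq2, 5 of the 7 passed: MC9 (adjusted p = 0.000388), RNS3 (0.00515), EXI1 (0.00913), PASPA3 (0.0139) and BFN1 (0.0401).

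Genes of root cap identity and maturation were also lower as a group, by less. Of the 14 members 13 were tested, with a median log2 fold change of -0.41 and 10 lower (camera adjusted p = 0.000647, or adjusted p = 0.560 with an estimated correlation). The largest difference was in RCPG (AT1G65570), a polygalacturonase gene of the outer root cap, at 36.0 ± 14.1 CPM in wild type and 11.1 ± 4.35 CPM in hsl2 (SD, n = 3), a log2 fold change of -1.70 with a standard error of 0.34 (adjusted p = 0.138 with edgeR and 0.000121 with DESeq2). The cellulase genes CEL5 (AT1G22880) and CEL3 (AT1G71380) had log2 fold changes of -0.82 and -1.10, with overlapping libraries. The NAC transcription factor genes of the root cap had values of -0.65 for BRN2, -0.57 for FEZ, -0.49 for BRN1 and -0.22 for SMB. SMB was at 41.5 ± 3.37 CPM in wild type and 35.7 ± 9.09 CPM in hsl2 (SD, n = 3). Adjusted over the list alone, RCPG, BRN2, CEL3, CEL5 and the auxin response factor gene ARF16 passed, 5 members and all lower, against 0 over all genes tested. The mean log2 CPM of the list, relative to its mean over all libraries, was 0.24, 0.51 and -0.05 in wild type 1, 2 and 3. It was -0.44, -0.08 and -0.19 in hsl2 1, 2 and 3, so that wild type 3 lay close to hsl2 2. Without the hsl2 1 library, which carried the green tissue transcripts, the list had a median of -0.40 and missed the threshold (camera adjusted p = 0.0649).

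Across the whole transcriptome the gene with the smallest p was JAL33 (AT3G16450), a mannose-binding lectin gene. It was at 18.0 ± 3.75 CPM in wild type and 5.29 ± 0.305 CPM in hsl2 (SD, n = 3), a log2 fold change of -1.77 with a standard error of 0.19 (adjusted p = 0.0662, edgeR). GI (AT1G22770) was at 77.7 ± 15.04 and 32.8 ± 3.995 CPM, the raffinose synthase family gene DIN10 (AT5G20250) at 304.3 ± 109.1 and 91.6 ± 14.8 CPM, the pyruvate orthophosphate dikinase gene PPDK (AT4G15530) at 12.9 ± 1.27 and 5.71 ± 0.688 CPM, and the sugar transporter gene STP4 (AT3G19930) at 43.5 ± 4.85 and 23.4 ± 1.04 CPM (SD, n = 3). HMT3 (AT3G22740), which encodes a homocysteine methyltransferase, and AT5G44417 had log2 fold changes of -1.74 and -1.41. Among the genes with higher values in hsl2, PPa5 (AT4G01480) was at 32.1 ± 6.42 and 70.5 ± 4.54 CPM and the cyclin gene CYCP3;2 (AT3G60550) at 6.28 ± 0.590 and 15.4 ± 3.35 CPM (SD, n = 3). The oxygenase family gene AT2G48080, the rubber elongation factor family gene AT1G67360 and the small GTPase gene RABA2c (AT3G46830) had log2 fold changes of 1.19, 0.76 and 0.79. JAL33 lies among similar tandem lectin genes, so the assignment of its reads is uncertain.

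With edgeR, 0 of 17989 genes passed an adjusted p of 0.05, and 2436 had an unadjusted p under 0.05, of which 1355 were higher and 1081 lower in hsl2. DESeq2 called 292 genes on the same counts, 165 higher and 127 lower, and limma-voom 0. Each of the 292 had the same direction in edgeR and an unadjusted edgeR p under 0.05. Without the hsl2 1 and wild type 3 libraries, a choice made after the data were seen, edgeR called 1311 genes, 816 higher and 495 lower. Wild type 3 is the wild type library nearest to hsl2 2 and hsl2 3 on both components, so that leaving it out favours a larger difference, and edgeR called 55 genes without it alone.

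**Figure D2:**
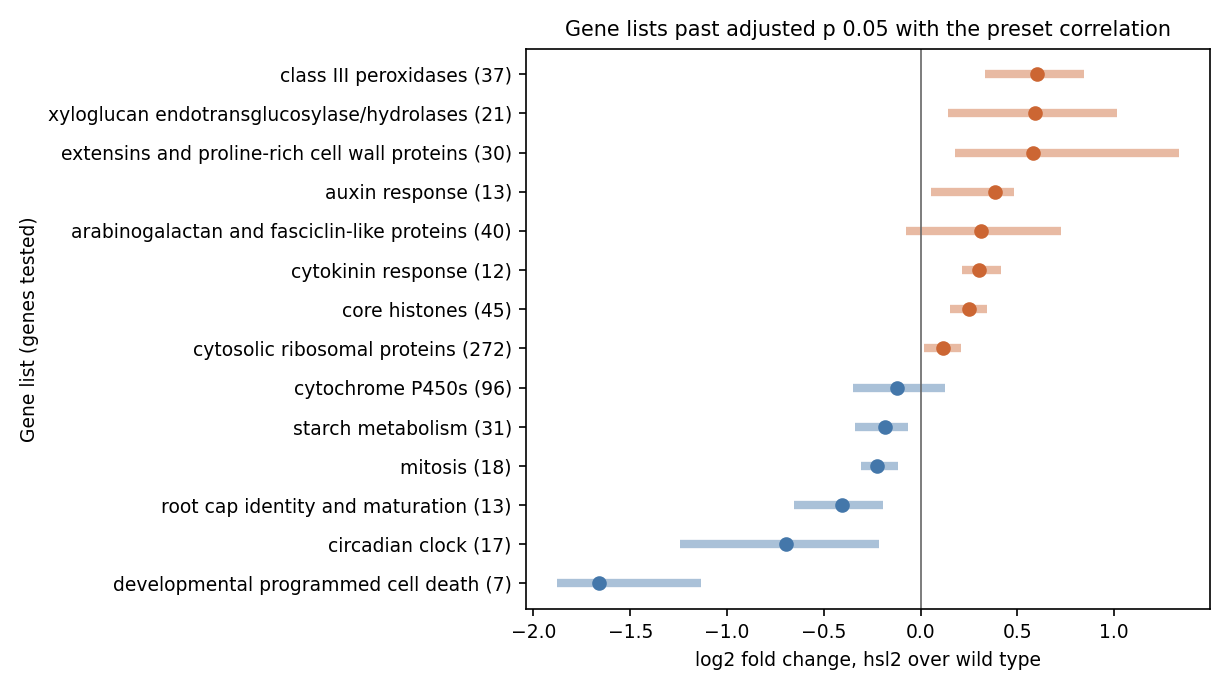
Median (point) and range from the lower to the upper quartile (bar) of the log2 fold change, hsl2 over wild type, for the members of each of the 14 gene lists past the camera threshold with the preset correlation. Lists with medians above 0 are orange and those below 0 blue. The cell death list has the lowest median, -1.66, and 3 cell wall related lists have the highest, from 0.58 to 0.60.

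Of 11 lists of wall-related genes, 4 were higher in hsl2 and 7 did not pass. The xyloglucan endotransglucosylase/hydrolases, which cut and rejoin wall xyloglucan, had a median log2 fold change of 0.59 over 21 tested genes, 18 of them higher (camera adjusted p = 3.30e-05, or adjusted p = 0.355 with an estimated correlation). XTH21 was at 10.2 ± 3.63 CPM in wild type and 23.1 ± 2.56 CPM in hsl2, XTH17 at 28.9 ± 9.33 and 58.4 ± 9.36 CPM, and XTH19 at 88.0 ± 7.11 and 149.3 ± 22.9 CPM (SD, n = 3). With DESeq2 these 3 and XTH18 were higher (adjusted p = 0.000850, 0.00592, 0.00120 and 0.0193). The class III peroxidases had a median of 0.60 over 37 tested genes, 29 higher (camera adjusted p = 1.54e-05, or adjusted p = 0.556 with an estimated correlation), led by AT4G16270 at 11.9 ± 3.93 and 28.3 ± 1.60 CPM and RCI3 at 196.7 ± 51.9 and 341.9 ± 25.8 CPM (SD, n = 3). Arabinogalactan and fasciclin-like proteins had a median of 0.31 over 40 tested genes, 26 higher and 14 lower (camera adjusted p = 0.000524, or adjusted p = 0.355 with an estimated correlation), with log2 fold changes of 1.25 for AGP13, 1.04 for AGP24 and 0.79 for AGP12. Extensins and related proline-rich proteins had a median of 0.58 over 30 tested genes, 26 higher (camera adjusted p = 9.65e-05, or adjusted p = 0.560 with an estimated correlation), with 1.69 for MOP10 and 1.65 for AT2G47540.

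Adjusted over each list alone, 7 xyloglucan enzymes, 9 peroxidases, 9 arabinogalactan or fasciclin-like proteins and 0 extensins passed, all higher, against 0 over all genes tested. The wild type 3 library, which carried the root hair transcripts, stood apart from the other wild type libraries in these groups: the mean log2 CPM of the xyloglucan enzymes, relative to their mean over all libraries, was 0.09 there, -0.45 and -0.61 in wild type 1 and 2, and 0.25 to 0.40 in hsl2. For extensins it was 0.36 in wild type 3 against -0.60 and -0.93 in wild type 1 and 2, and -0.03, 0.33 and 0.87 in hsl2, and without wild type 3 their median log2 fold change was 0.87 (camera adjusted p = 7.98e-08). The root hair and epidermis list itself had a median log2 fold change of 0.62 over 12 genes and missed the threshold (camera adjusted p = 0.0660). It passed without wild type 3, with a median of 1.21 (camera adjusted p = 0.000640), and with the replicate number as a block (0.00492). Within that list the hair cell genes COBL9 and RSL4 had log2 fold changes of 1.28 and 1.13, and GL2, which represses hair fate, was at 36.1 ± 6.11 CPM in wild type and 22.3 ± 3.21 CPM in hsl2 (SD, n = 3). Among the other wall-related lists, expansins (median 0.18), pectin methylesterases and pectate lyases (0.03), pectin lyase-like proteins (0.03), polygalacturonases (0.13), GH9 cellulases and beta-xylosidases (0.04), pectin methylesterase inhibitors (-0.05) and subtilases (-0.12) did not pass (camera adjusted p = 0.190, 0.708, 0.513, 0.911, 0.911, 0.324 and 0.324). Pectin lyase-like proteins passed without hsl2 1 (camera adjusted p = 0.0310), and expansins (0.0163) and pectin methylesterases and pectate lyases (0.0174) without hsl2 1 and wild type 3. Without hsl2 1 alone the expansin median was 0.09.

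Circadian clock genes were lower in hsl2 as a group, with a median log2 fold change of -0.69 over 17 tested genes, 13 lower and 4 higher (camera adjusted p = 0.000427, or adjusted p = 0.355 with an estimated correlation). With fry, which asks whether the members move one way on balance, it was the 1 list that passed (adjusted p = 0.00529). Adjusted over the list alone, 6 genes passed, all lower, and the same number passed with DESeq2. They were GI, the pseudo-response regulators PRR9, PRR7 and PRR5, and the coactivators LNK1 and LNK2. PRR7 was at 23.2 ± 5.94 CPM in wild type and 8.57 ± 3.07 CPM in hsl2, PRR5 at 28.3 ± 2.54 and 15.3 ± 3.48 CPM, LNK1 at 21.8 ± 11.02 and 8.01 ± 0.766 CPM, and PRR9 at 2.47 ± 1.32 and 0.555 ± 0.228 CPM (SD, n = 3). TOC1, the evening regulator, was at 82.2 ± 10.2 and 70.9 ± 5.06 CPM (SD, n = 3). The morning genes CCA1 and LHY were near 1 CPM and varied more within wild type than between genotypes: CCA1 was at 0.639, 2.28 and 0.121 CPM in wild type 1, 2 and 3.

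**Figure D3:**
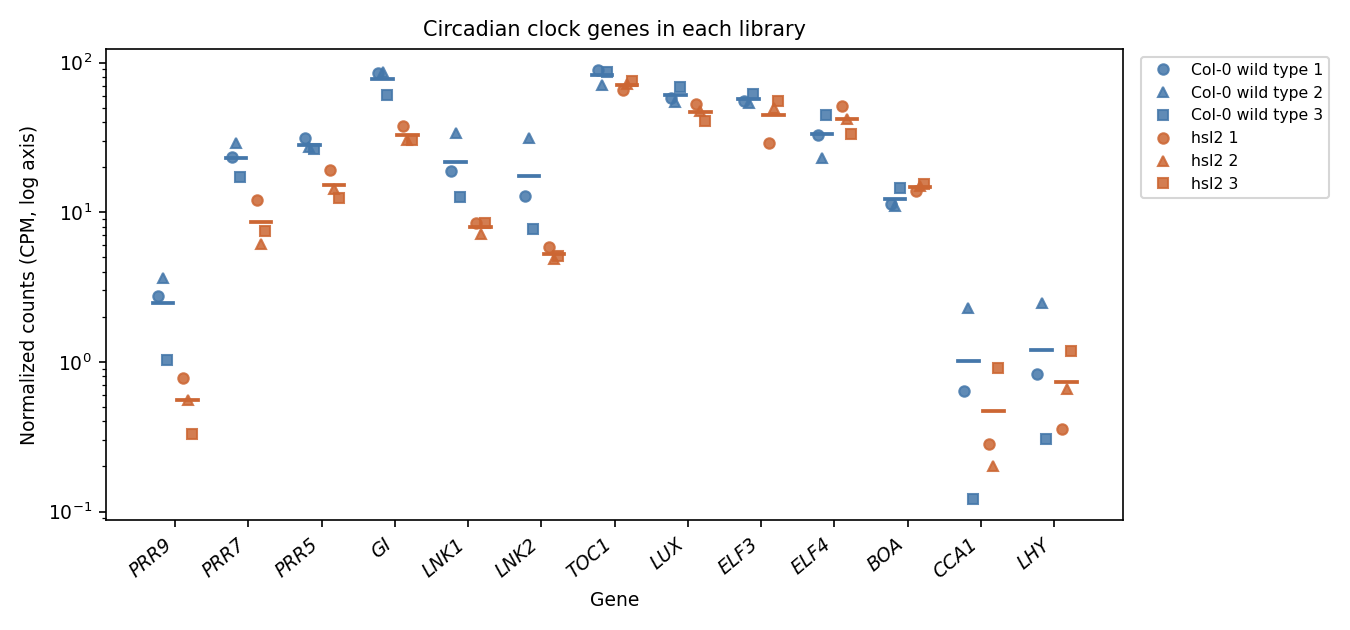
Normalized counts (CPM, log axis) of 13 circadian clock genes in each library, with symbols for replicates and bars for the mean of 3 libraries per genotype. PRR9, PRR7, PRR5, GI, LNK1, LNK2 and the evening gene LUX are lower in each hsl2 library than in any wild type library, while TOC1, ELF3, ELF4, BOA, CCA1 and LHY overlap.

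Starch metabolism genes, which serve the gravity-sensing columella among other tissues, were lower as a group by a small amount, with a median log2 fold change of -0.18 over 31 tested genes, 24 lower (camera adjusted p = 0.000885, or adjusted p = 0.560 with an estimated correlation). The alpha-amylase gene AMY3 (AT1G69830), at 43.3 ± 6.40 CPM in wild type and 24.8 ± 1.54 CPM in hsl2 (SD, n = 3), was the 1 member that passed over the list alone and the 1 with DESeq2 (adjusted p = 0.000783). PWD, ISA3 and PHS2, which also act in starch breakdown, had log2 fold changes of -0.50, -0.36 and -0.38.

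The cytokinin and auxin response lists were higher in hsl2. The cytokinin response list had a median log2 fold change of 0.30 over 12 tested genes, 11 higher (camera adjusted p = 0.000657, or adjusted p = 0.556 with an estimated correlation). The response regulator gene ARR3 (AT1G59940) was at 22.9 ± 3.82 CPM in wild type and 45.01 ± 6.70 CPM in hsl2 (SD, n = 3) and passed with DESeq2 (adjusted p = 0.000191). CKX3, ARR4 and ARR9 had log2 fold changes of 0.93, 0.41 and 0.42, and these 4 members passed over the list alone, against 0 over all genes tested. Without hsl2 1 and wild type 3 the median was 0.50 (camera adjusted p = 0.00291). The auxin response list had a median of 0.39 over 13 tested genes, 12 higher (camera adjusted p = 0.00172, or adjusted p = 0.355 with an estimated correlation), with 1.22 for IAA3 and 0.48 for IAA17, 0 members past the threshold over the list alone, and a camera adjusted p of 0.133 without the filter on low counts. The ethylene, jasmonate and immune response lists had medians of -0.10, 0.02 and -0.08 (camera adjusted p = 0.675, 0.918 and 0.681), and of 0.14, -0.06 and -0.27 without hsl2 1 (0.215, 0.341 and 0.341).

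Mitotic genes were lower as a group, with a median log2 fold change of -0.23 over 18 genes, 17 lower (camera adjusted p = 0.00511, or adjusted p = 0.819 with an estimated correlation), including CDC20.2 at -0.36 and CYCB2;3 at -0.34. The call was lost without wild type 1 (camera adjusted p = 0.273) and without hsl2 2 (0.0578). Core histones were higher, with a median of 0.25 over 45 genes, 38 higher (camera adjusted p = 3.30e-05, or adjusted p = 0.560 with an estimated correlation), and their mean log2 CPM relative to all libraries was 0.26 in hsl2 1, the library with green tissue transcripts, and at most 0.06 in hsl2 2 and 3. Without hsl2 1 the histone median was 0.13 (camera adjusted p = 0.00418). Ribosomal proteins had a median of 0.12 over 272 genes, 215 higher (camera adjusted p = 0.00985, or adjusted p = 0.904 with an estimated correlation), with 0.31 in hsl2 1 on the same scale. Without hsl2 1 their direction turned, with a median of -0.06 (camera adjusted p = 0.163), and without wild type 3 the call was lost (0.529). Cytochrome P450s had a median of -0.12 over 96 genes, 63 lower and 33 higher (camera adjusted p = 0.0205, or adjusted p = 0.560 with an estimated correlation). The call was lost without the filter on low counts (camera adjusted p = 0.408) and without wild type 2 (0.132), wild type 3 (0.0713) or hsl2 3 (0.314), while without hsl2 1 the median was -0.20 (0.00351). CYP81F4, of indole glucosinolate synthesis, was at 150.7 ± 17.5 CPM in wild type and 89.0 ± 13.0 CPM in hsl2 (SD, n = 3), and passed with DESeq2 (adjusted p = 0.00145).

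The markers of other root cell types did not pass as lists. Medians were 0.82 for xylem, 0.14 for endodermis, 0.21 for phloem and -0.04 for the stem cell niche (camera adjusted p = 0.154, 0.586, 0.911 and 0.989). Xylem genes passed without hsl2 1, with a median of 1.18 (camera adjusted p = 0.000199), and with the replicate number as a block (0.0136). The niche regulators SCR and SHR were at 66.4 ± 0.851 and 48.7 ± 6.42 CPM in wild type, and 64.6 ± 11.8 and 50.7 ± 7.93 CPM in hsl2 (SD, n = 3). The green tissue list had a median of 0.29 (camera adjusted p = 0.329) with hsl2 1 included and -0.28 without it, and passed without hsl2 2 (0.0234) or hsl2 3 (0.0199). DNA replication (median -0.20), receptor-like kinases (-0.08) and glucosinolate metabolism (-0.12) each had a camera adjusted p of 0.0660. DNA replication passed without wild type 3, with a median of -0.32 (camera adjusted p = 0.00362). Receptor-like kinases passed without wild type 1 (0.00592), hsl2 2 (0.0220) or hsl2 3 (0.00496), but their direction turned without hsl2 1 and wild type 3 (0.818). Phosphate starvation (-0.09), sulfur deficiency (0.32), iron deficiency (-0.22), hypoxia (0.15) and touch and wounding (-0.06) did not pass (camera adjusted p = 0.496, 0.652, 0.683, 0.586 and 0.902). The sulfur deficiency median was 0.04 without hsl2 1 and 0.15 without wild type 3. Without hsl2 1 the medians of endodermis, hypoxia and the stem cell niche had the other sign (-0.12, -0.12 and 0.08), as had those of phloem and phosphate starvation without wild type 3 (-0.07 and 0.16). The mean and the median differed in sign for polygalacturonases, GH9 cellulases, hypoxia and the stem cell niche. Heat shock proteins had fewer than 5 tested genes.

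The region around HSL2 was examined because a mutant line can carry linked differences. Of 388 tested genes within 1 Mb of HSL2, 0 passed with edgeR. In a comparison added after the data were seen, 55 had an unadjusted p under 0.05, which is 14.2% against 13.5% of all other tested genes (two-sided Fisher's exact p = 0.708). DESeq2 called 4 genes in this window: the clock gene LNK1 (log2 fold change -1.45, adjusted p = 0.00107), AT5G67390 (0.85, 0.00426), the peroxidase gene AT5G64100 (0.98, 0.0435) and the defensin-like gene PDF2.5 (0.47, 0.0482).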

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

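The fits with library quality weights and without hsl2 1 and wild type 3 were chosen after the data were seen. Against 0 genes with edgeR, the count of genes past the threshold stayed at 0 with RLE size factors, upper-quartile normalization, the stricter filter, limma-voom, a threshold of 0.01 and the test against a fold change of 1.5. The median log2 fold change of all genes lay between -0.02 and 0.01 in all settings. DESeq2 called 292 genes (165 higher, 127 lower), no filter on low counts 110 (49 higher, 61 lower, with 106 of the 110 shared with DESeq2), voom with quality weights 1836 (1172 higher, 664 lower), and edgeR without hsl2 1 and wild type 3 together 1311 (816 higher, 495 lower). Leaving out 1 library gave 0 to 55 genes, with 0 to 42 higher and 0 to 13 lower: 55 without wild type 3, JAL33 without wild type 1, DIN10, ATCTH and RMA1 without wild type 2, NRT1.5 without hsl2 3, and 0 without hsl2 1 or hsl2 2. Within 1 Mb of HSL2, 0 genes passed with edgeR, 4 with DESeq2, 2 without the filter (LNK1 and AT5G67390) and 0 to 1 with 1 library left out (LNK1 without wild type 3). The replicate number as a block gave 52 genes (23 higher, 29 lower), 51 of them shared with DESeq2. Samples with the same number correlated in their deviations from the group means by 0.138, 0.0645 and 0.0204, which does not show that the numbers pair them, and wild type 3 correlated best with hsl2 2. The cause of these differences was not tested.

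Of 39 gene lists, 14 passed with the preset correlation, 0 with an estimated correlation, 1 with fry, and 12 to 19 in the other settings; the 14 lists kept their direction in all settings except the cytosolic ribosomal proteins. The adjusted p of the list cytosolic ribosomal proteins ran from 1.34e-06 without hsl2 2 to 0.529 without wild type 3, and their direction turned without hsl2 1 (adjusted p = 0.163) and without hsl2 1 and wild type 3 (0.00355). Over 88 named genes, 1060 of 1228 alternative values kept direction and did not pass, as with edgeR on all libraries. A further 159 passed with the same direction, and 9 had the other sign. Those 9 belonged to clock genes with values near 0 or large spread. Many of the genes were named for a small p in these data, which by itself favours a kept direction. With 1 library left out, the log2 fold change of CCA1 ran from -2.04 to 0.20, of LHY from -1.18 to 0.32, and of RVE8 from -1.47 to 0.14, each highest without wild type 2. RVE1 ran from -0.22 to 0.30, being -0.16 without wild type 2, -0.22 without hsl2 2 and -0.04 without hsl2 3. RVE7 ran from -0.59 to 0.0582, the latter without wild type 3, and was 0.0934 without hsl2 1 and wild type 3. GRP7 ran from -0.0652 without hsl2 1 to 0.35. In the simulated data, with 3 libraries per genotype, edgeR recovered 5.97% of changes of 1.5-fold. The simulation drew genes independently and held no outlying library, so it may overstate what edgeR can reach in the real data. Larger changes did not pass there either, such as DIN10 at 3.32-fold lower in hsl2 (adjusted p = 0.114, edgeR).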

Other observations

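The tests of root cap share, maturing tissue and time of day, the count of splits at an unadjusted p, and the camera tests and left-out libraries for gene groups in this part, were chosen after the results were seen, as were the gene groups of the ER body, carbon starvation and clock phase and the single genes named here.

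Transcripts of several ER body and lectin genes were lower in hsl2. ER bodies are endoplasmic reticulum compartments that hold beta-glucosidases, and jacalin lectins bind these enzymes. Of 16 tested genes of this set, 15 were lower, with a median log2 fold change of -0.54, and 10 passed with DESeq2. NAI1, the transcription factor for ER body formation, was at 31.0 CPM in wild type and 15.71 CPM in hsl2, the beta-glucosidase gene PYK10 at 1025 and 721.9 CPM, TGG4 at 95.9 and 27.5 CPM, and the lectin genes MLP-300B and JAL31 at 90.6 and 31.2 CPM and at 42.9 and 24.5 CPM. TGG4 and TGG5 are close copies of each other, as are several of the lectin genes, so reads may be shared among them. The group was drawn up after 8 of its genes had been seen to be lower, and most of the DESeq2 calls were among these. Its other 8 tested members, among them BGLU22 and JAL34, had a median of -0.48, with 7 lower and a percentile of 0 among 10000 random lists of like expression, which take no account of correlation between genes. With an estimated correlation these 8 had an unadjusted camera p of 0.0211, and their median lay between -0.54 and -0.40 with 1 library left out. In 3 of these 8 the libraries of the genotypes overlapped.

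Among genes induced when sugar runs low, differences depended in part on wild type 3. Of 13 tested genes 12 had a log2 fold change below 0, with a median of -0.62, and 2 passed with DESeq2, DIN10 and the trehalose phosphate synthase family gene TPS11 at 28.2 CPM in wild type and 13.5 CPM in hsl2. ASN1, an asparagine synthetase gene, was at 5.51, 0.985 and 26.2 CPM in wild type 1, 2 and 3 and at 0.393 to 1.37 CPM in hsl2, with overlapping libraries. Its log2 fold change of -3.58 was -1.88 without wild type 3, and it did not pass with DESeq2 (adjusted p = 0.113). Without DIN10, which had prompted the group, 12 tested members had a median of -0.51, with 11 below 0 and a percentile of 0 among 10000 random lists. Of these 12, 11 were highest in wild type 3 and 10 had overlapping libraries. Their median was -0.35 without wild type 3 and -0.20 without it and hsl2 1, and with an estimated correlation their unadjusted camera p was 0.165. Other genes that passed with DESeq2 included the glyoxylate cycle gene ICL at 63.1 and 28.3 CPM, the iron superoxide dismutase gene FSD1 at 4.26 and 17.2 CPM, and the lipid transfer protein family genes AT4G12510 and AT4G12520 at 14.8 and 46.1 CPM and at 36.2 and 95.4 CPM in wild type and hsl2, with adjusted p = 0.000191, 2.94e-05, 0.000476 and 1.08e-05.

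The lower level of the cell death genes in hsl2 was the pattern closest to the purpose of the series, and the list did not pass with an estimated correlation (camera adjusted p = 0.355). A smaller share of all root cap tissue in the hsl2 tips, as from a longer piece of root, would lower the cap regulators alike, but SMB, FEZ, BRN1, BRN2 and ACR4 had a median log2 fold change of -0.49 against -1.66 for the cell death genes (two-sided exact permutation over genes, p = 0.00631). The regulators were thus lowered less than the cell death genes, but this comparison was chosen after the results were seen, so its p is no independent support. The permutation also treats genes as independent and does not measure spread between samples. RCPG, an outer root cap gene outside this set of regulators, was about as low as the cell death genes. A smaller share of cap tissue therefore stays open. Removing the trend with GC content and transcript length left the median at -1.71. An effect of the mutation on the last stage of cap cells, or a loss of only the outermost cap layers before or during collection, may each account for the pattern and were not tested.

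Of the cell wall lists 4 were higher in hsl2 with the preset correlation but did not pass with an estimated one (camera adjusted p from 0.355 to 0.560), and the root hair list missed the threshold. More maturing tissue in the hsl2 tips, as from a longer piece of root, stays open. Pooled endodermis, xylem and phloem markers had a median log2 fold change of 0.23, at the 97.7 percentile of 10000 random lists, and the mitotic genes -0.23. But the pooled markers had an unadjusted camera p of 0.431 with an estimated correlation, and their median was 0.11 without hsl2 3. Without hsl2 1 and wild type 3 it was 0.13, with an unadjusted camera p of 0.00746 at the preset correlation, against 0.162 with all libraries. Without hsl2 1 the endodermis median was -0.12 and the xylem median 1.18, and without wild type 3 the phloem median was -0.07. The trend with GC content and length does not account for the xyloglucan enzymes, whose median was 0.49 after its removal and 0.59 before. Wild type 3 shared the root hair transcripts, so the position of the tip in the piece collected may vary between samples as well as genotypes. An effect of the mutation on cell maturation stays open and was not tested.

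The 6 clock genes GI, PRR9, PRR7, PRR5, LNK1 and LNK2, grouped here as day-phased, were lower in hsl2. No phase was measured in these samples. Their median log2 fold change was -1.44, against -0.21 for 5 evening-phased genes, of which LUX was lower in each hsl2 library, but they were grouped after they had been seen to be lower, so this contrast tests nothing. Tips collected at another time of day stay open as an explanation, since the time of collection is not given in the sources used here. Wild type 2, the library with the highest LNK2 and CCA1, was not the whole source, since the median without it was -1.07. An effect of the mutation on the clock stays open and was not tested.

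The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. With edgeR, the real split gave 0 genes past the threshold and the highest of the other splits 0, so that all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 2436 genes and the highest other 1573, which makes it the 1 split with as many. For gene lists the real split gave 14 and the highest other 18, and 5 splits gave at least 14. Wild type 1, hsl2 1 and hsl2 2 against the rest gave 13 lists, with 159 genes at an unadjusted p under 0.05. Camera with the preset correlation thus called lists also where few genes differed, so passing it does not by itself show an effect of genotype. The split with 18 lists set wild type 1, wild type 2 and hsl2 1 against the rest, which is the order of the second principal component, and points to a structure of the samples beside genotype.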
